A study of Mus musculus with 16 samples.

How the data were processed

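RNA from sorted LSK cells of 16 samples was sequenced: 5 wild-type and 5 mutant samples after PBS, and 3 wild-type and 3 mutant samples after 250 mg/kg 5-FU, all taken 10 days after injection. Per the labels, the mice were 8 to 14 weeks old on a C57BL/6J background, 3000 to 10000 cells were sorted per replicate, RNA was purified with the RNeasy Micro kit, and libraries were made with the NuGEN Ovation Ultralow system. RSEM 1.3.1 and FastQC 0.11.2 with the mm10/GRCm38 genome were named, per the submitters' processing notes. The aligner, the annotation release and any filter on reads are not given in the sources used here. Per the file headers, the authors deposited for each sample and gene the RSEM expected count, an estimate of fragments per gene that is not scaled to the library. Per the file headers, the deposited tables also hold TPM, scaled to 1e6 transcripts, and FPKM, scaled to effective length and to 1e6 fragments. Gene length and effective length stand beside them in the deposited tables. The expected counts served for the tests, the TPM values for 1 alternative test, the effective lengths for the check of transcript length, and FPKM and gene length only for checks of the tables.

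Total expected counts ran from 19.37 to 28.88 (in units of 1e6) per library, and between 18139 and 21128 genes were above 0. A count of 3, taken as the floor for a gene read 0 times in a library, came to between 0.0798 and 0.272 CPM. The 10 most abundant genes held between 2.49 and 47.9% of the counts. Gene IDs were matched to GENCODE M21 (GRCm38) without their version numbers: 53237 of 53342 (99.8%) were found, 93.4% of these with the same symbol. Symbols are those in the deposited tables, and coordinates are those of GENCODE M21, counted from 1.

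Expected counts were rounded to whole numbers. Genes with too few counts were removed with filterByExpr of edgeR 4.0.16 (minimum count 10), which left 16482. Libraries were scaled with TMM factors between 0.508 and 1.37, computed with the immunoglobulin genes included, and CPM values use these factors. The quasi-likelihood F test of edgeR (robust fit, 1 mean per group, all 16 samples) compared the mutant with wild type under PBS and after 5-FU, 5-FU with PBS in wild type and in the mutant, and the responses to 5-FU between genotypes (the interaction). P values were adjusted by the method of Benjamini and Hochberg over all genes tested in a comparison, with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of F. Groups were also compared by exact two-sided permutation tests for the immunoglobulin share and, on log2 CPM, for Gata2, Kit and Ly6a (12 tests). These permutation tests took no account of replicate numbers. A gene with 0 counts in a group has its fold given against the floor of 3 counts per library, as a lower bound. For genes with 1 to 3 counts in 1 of 2 groups compared a 95% counting interval of the fold is given where the 2 values are printed; none is given for the interaction. The fitted log2 fold change of such genes is not a bound, and medians of lists that hold such genes are not bounds either.

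The named genes were Gata2, Kit and Ly6a in every comparison. To these came, among genes with an adjusted p under 0.05, an absolute log2 fold change of at least 1, a mean of at least 5 CPM in the higher group and, except for the interaction, no overlap between the replicates of the groups, the 12 with the largest rise and the 12 with the largest fall. Predicted or unnamed gene models, Xist and Y-linked genes were passed over. Some genes that met these rules are not reported here, and counts of named genes include them. The genes eligible as rises and falls numbered 3 and 0 for genotype under PBS, 151 and 57 for genotype after 5-FU, 485 and 731 for 5-FU in wild type, 97 and 130 for 5-FU in the mutant, and 65 and 5 for the interaction. From each gene list the 2 to 4 members with the smallest p were named. For the lymphoid-primed list, the names of all rises between genotypes after 5-FU and for the interaction were added later. Of 33 lists of genes for blood cell types and cell processes, 32 had members to test; the list of mitochondrially encoded genes had too few and was left out. Each list was tested with camera of limma 3.58.1 on voom log2 CPM with a preset correlation of 0.01, and P values were adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. Camera compares a list with the other genes, while fry asks whether its genes move on balance in one direction and makes no comparison with other genes. Beside the counts of members past the threshold over all genes stand counts adjusted over the list alone. The comparisons, tests, lists, naming rule and alternatives below were set before the data were examined, apart from those said to have been added later.

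The alternatives were scaling with RLE or the upper quartile; the DESeq2 1.42.0 Wald test; limma-voom with sample quality weights; limma-trend on log2(TPM + 1) for genes with a TPM of at least 1 in at least 3 samples; no low-count filter, or filters of 1 or 5 CPM in at least 3 samples; a fit that is not robust; only the 2 groups compared; the replicate number as a block; the writing of the sample code as a covariate; only samples with the same code writing or the same code prefix; a minimum log2 fold change of 1; sex-linked genes left out; and each library left out in turn. Alternatives added after the data were seen were immunoglobulin genes left out, the immunoglobulin share as a covariate, wild-type PBS replicate 3 with mutant PBS replicate 3 left out, the replicate block in the PBS groups alone, and the length trend removed. For the last, a lowess trend of log2 CPM with log2 effective length was taken for each library over genes that are not immunoglobulin genes, and served as an offset in edgeR and was taken from the voom values; camera was run on these with the preset and with an estimated correlation. The ribosomal protein, oxidative phosphorylation and histone lists were also tested with camera on the signed root of the edgeR F statistic, from which its lowess trend with length was taken, with adjustment over 3 lists in 5 comparisons. Whether replicate numbers pair the samples was checked by correlating deviations from the group means. All 5 same-numbered pairs of wild-type and mutant PBS samples had r over 0.1 (0.16 to 0.57, median 0.34), so the numbers were taken to pair the PBS groups. The labels do not say what a number marks. Same-numbered PBS samples also share the code writing, the sex-linked transcripts read (Y-linked or Xist) and the rank of immunoglobulin share within their group. The correlation r was not set apart from any of these. A list of 25 plasma cell genes without immunoglobulin genes was also added then.

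The edgeR steps were tested on counts drawn from negative binomial distributions with the mean level and dispersion of each real gene and the real library sizes, with 50 genes changed at each fold size. With a 4-fold change, 90% were recovered for genotype under PBS (16145 genes), 80% for genotype after 5-FU (16073), 86% for 5-FU in wild type (16120), 86% for 5-FU in the mutant (16220) and 62% for the interaction (16164). With a 2-fold change the recovered shares were 32%, 4%, 14%, 14% and 0% in the same order, and false calls made up 4.2%, 2.2%, 0.7%, 5.2% and 3.2% of all calls. Camera called 0 of 100 unchanged and 20 of 20 raised simulated lists for 5-FU in wild type. Simulated genes were drawn independently, without correlation between genes, so these shares do not show how the tests behave with it. The changed genes for edgeR were drawn from the more abundant ones, so the recovered shares do not cover genes near 0 counts. Calculations used R 4.3.3, and figures Python 3.11.15 with matplotlib 3.10.9.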

Results

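Gene expression was measured by RNA sequencing in LSK cells, the lineage-negative, Sca-1-positive and c-Kit-positive fraction of mouse bone marrow that holds hematopoietic stem cells and multipotent progenitors. The cells came from wild-type mice and from mice homozygous for a C-to-T change in an Ets motif of the Gata2 +9.5 enhancer, a regulatory element within an intron of Gata2 (called the mutant here). Mice had received PBS or 250 mg/kg 5-fluorouracil (5-FU), a drug that kills dividing blood cells, 10 days before the cells were sorted. The 16 libraries formed 4 groups: wild type with PBS (n = 5), mutant with PBS (n = 5), wild type with 5-FU (n = 3) and mutant with 5-FU (n = 3). Total counts per library ran from 19.37 to 28.88 (in units of 1e6), with group means of 22.71 ± 3.19 (SD), 23.7 ± 2.47, 24.14 ± 4.04 and 26.91 ± 1.85 in that order. Of 53342 genes, 16482 were tested. The labels do not say whether the replicates were separate mice, so every p measures the spread between these samples.

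Gata2 (chromosome 6, 88193891 to 88207032, plus strand, mm10/GRCm38) encodes a zinc-finger transcription factor that hematopoietic stem cells need. Because the substitution lies in an intronic enhancer and leaves the transcript intact, the level of Gata2 mRNA does not check the genotype labels. In CPM (counts scaled to a library of 1e6), Gata2 stood at 62.6, 57.5, 54.1, 81.8 and 113 in wild-type PBS replicates 1 to 5. The mutant PBS replicates 1 to 5 had 109, 72.8, 48.4, 164 and 167 CPM. After 5-FU the wild-type replicates 1 to 3 had 204, 224 and 192 CPM and the mutant replicates 1 to 3 had 169, 208 and 197 CPM. Group means were 73.8 ± 24.5 (SD, n = 5), 112 ± 53.1 (n = 5), 207 ± 16.4 (n = 3) and 191 ± 20.4 (n = 3) CPM. Within each PBS group, Gata2 was lower the higher the share of a library's counts from immunoglobulin genes. In wild-type PBS it ran from 113 CPM at a share of 6.37% to 54.1 CPM at 44.24%. In mutant PBS it ran from 167 CPM at 3.67% to 48.4 CPM at 50.17%. The wild-type 5-FU libraries held 0.04 to 0.33%, so their Gata2 level was not set apart from this share. Mutant 5-FU replicate 1 had 169 CPM at a share of 26.57%.

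The wild-type 5-FU group had more Gata2 than the wild-type PBS group, with a log2 fold change of 1.48 ± 0.33 (SE) and an adjusted p of 0.0103. Every wild-type 5-FU library lay above every wild-type PBS library; the exact two-sided permutation p was 0.0179, the smallest these group sizes allow, and 0.215 after adjustment over 12 such tests. Within the mutant, Gata2 differed by 0.77 ± 0.34 after 5-FU (adjusted p = 0.329), and the difference between the genotypes in this response was −0.71 ± 0.48 (adjusted p = 0.602). Between genotypes, Gata2 differed by 0.60 ± 0.30 under PBS (adjusted p = 1; exact two-sided permutation p = 0.23) and by −0.11 ± 0.38 after 5-FU (adjusted p = 0.894; exact two-sided permutation p = 0.5). Each sample carries a code in its label, written with a leading zero in replicates 1 to 3 of both PBS groups and of the mutant 5-FU group, and without one in the other libraries. The labels do not say what the codes mean. Among wild-type libraries with the same writing, Gata2 rose by 1.07 (adjusted p = 0.0154), and within 1 shared code prefix, which holds a single wild-type 5-FU library, the difference was 0.97 (adjusted p = 0.129). In the mutant these differences were 1.29 (adjusted p = 0.0891) and 1.07 (adjusted p = 0.0586). Over the 18 alternatives tried, the log2 fold change in wild type ran from −0.59 to 2.95 and its adjusted p from 3.96e-05 to 0.672; the direction turned (−0.59, adjusted p = 0.672) with the immunoglobulin share as a covariate, chosen after the data were seen, and the adjusted p was 0.0581 without wild-type 5-FU replicate 2 (1.43). In the mutant the adjusted p ran from 0.00448 to 0.783 over 18 alternatives, and Gata2 passed by limma-voom with sample quality weights (0.83, adjusted p = 0.041), with code writing as a covariate (1.24, 0.00448) and with the replicate number as a block (1.28, 0.0051), although the numbers do not pair these groups. Between genotypes after 5-FU the value turned to 0.82 (adjusted p = 0.406) with code writing, to 1.78 (0.461) with the immunoglobulin share and to 0.01 (0.992) with the trend with transcript length removed, and that of the interaction to 0.27 and 1.33 with the same 2 covariates.

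Transcripts of the surface proteins that define the sorting gate were followed too. Kit, which encodes the c-Kit receptor, averaged 261, 204, 424 and 150 CPM in wild-type PBS, mutant PBS, wild-type 5-FU and mutant 5-FU. The genotypes differed in Kit after 5-FU by −1.50 ± 0.56 (adjusted p = 0.172). Ly6a, which encodes Sca-1, averaged 1300, 1180, 197 and 604 CPM. Its difference after 5-FU was −2.72 ± 1.04 in wild type (adjusted p = 0.0818), and the genotypes differed by 1.61 ± 1.05 after 5-FU (adjusted p = 0.408).

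**Figure D1:**
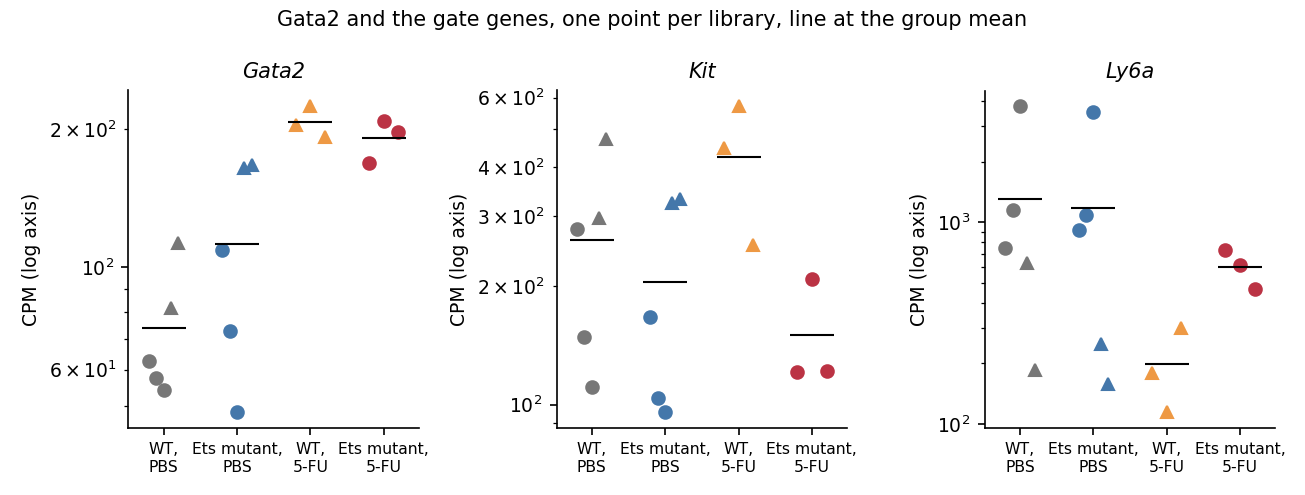
Gata2, Kit and Ly6a in CPM on log axes for the 16 libraries; each point is a library, circles carry sample codes with a leading zero, triangles codes without, and lines are group means. Gata2 lies between 192 and 224 CPM in the wild-type 5-FU libraries and between 54.1 and 113 CPM in the wild-type PBS libraries.

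Immunoglobulin genes, which plasma cells and B cells transcribe, took a large and uneven share of the counts. They held 28.6 ± 14.2% (SD, n = 5) of counts in wild-type PBS, 25.9 ± 18.4% (n = 5) in mutant PBS, 0.194 ± 0.147% (n = 3) in wild-type 5-FU and 16.4 ± 10.4% (n = 3) in mutant 5-FU. The share fell after 5-FU in wild type (exact two-sided permutation p = 0.0357); in the mutant the exact two-sided permutation p was 0.464. After 5-FU every mutant library lay above every wild-type library, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 can give. Jchain, the chain that joins antibody molecules, moved with the share, at 23120, 22710, 44.4 and 9166 CPM in wild-type PBS, mutant PBS, wild-type 5-FU and mutant 5-FU. The sorting gate removes cells with B220, CD3, CD4, CD5 or CD8 on their surface. Counts for immunoglobulin V genes, Bcl2a1a, Bcl2a1d, Hba-a1, Sirpb1a and Sirpb1c are uncertain, since near copies share their reads.

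**Figure D2:**
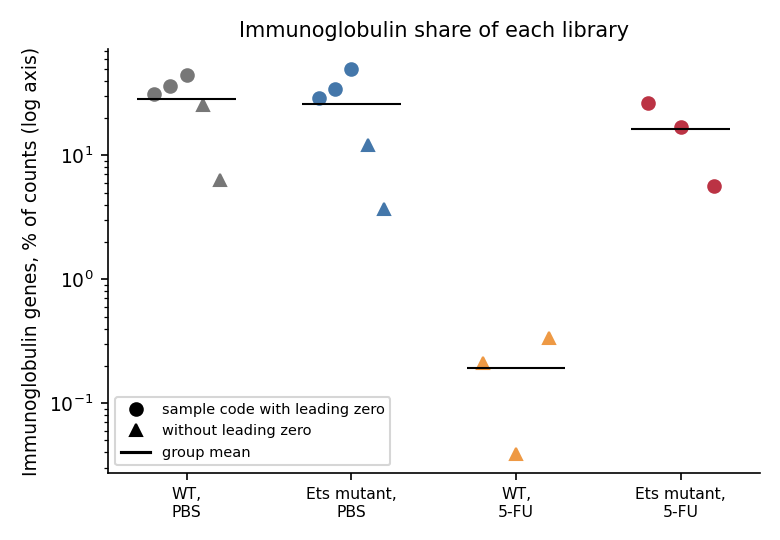
Share of counts from immunoglobulin genes in each library, in percent on a log axis; circles are libraries whose sample codes have a leading zero, triangles those without, and lines are group means. The wild-type 5-FU libraries lie between 0.04 and 0.33%, and the lowest of the others is at 3.67%.

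Under PBS, the comparison of mutant with wild type asks whether the enhancer substitution changes LSK cells at steady state. The edgeR test called 3 genes, all higher in the mutant, and 0 lower. An unadjusted p under 0.05 was reached by 541 genes where chance gives 824; DESeq2 called 26 genes (15 higher, 11 lower), limma-voom with sample quality weights 9, and limma-trend on TPM 0 (119 with an unadjusted p under 0.05). Slamf1, the CD150 receptor used to sort stem cells, was higher by 1.93 ± 0.21 (adjusted p = 0.000945), with 4.56 CPM in wild type and 17.5 CPM in the mutant. Hoxb2, a homeobox transcription factor, was higher by 1.92 ± 0.26 (adjusted p = 0.011), with 1.79 against 6.81 CPM. Selp, which encodes the adhesion molecule P-selectin of platelets and endothelium, was higher by 1.58 ± 0.22 (adjusted p = 0.011), with 11.5 against 34.4 CPM. For all 3 genes each of the 5 mutant libraries lay above each of the 5 wild-type libraries. Slamf1 lies on chromosome 1 (171767127 to 171801184), Selp on the same chromosome (164115264 to 164150026) and Hoxb2 on chromosome 11 (96350525 to 96354012). With the writing of the sample codes as a covariate all 3 stayed past the threshold. No code prefix (the digits of a code) occurs in both genotypes. A batch marked by the prefix therefore cannot be separated from genotype, under PBS or after 5-FU. The call ended for Hoxb2 without wild-type PBS replicate 4 (adjusted p = 0.0532) and for Selp without wild-type PBS replicates 1 (0.0564), 2 (0.0602) or 4 (0.111), and an edgeR fit of the PBS groups alone called 0 genes (318 with an unadjusted p under 0.05). With the replicate number as a block, which pairs the PBS samples, all 3 passed in the fit of all groups. In a blocked fit of the PBS groups alone, chosen after the data were seen, Selp passed (adjusted p = 0.0176), and Slamf1 (1.93) and Hoxb2 (1.96) each had an adjusted p of 0.0699.

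Of the 32 gene lists tested, camera placed 8 higher and 6 lower in the mutant under PBS; with an estimated correlation, and by fry, 0 lists were called. In the megakaryocyte and platelet list of 16 genes, 1 gene rose, 0 fell and 15 were not past the threshold; adjusted over the list alone, 3 rose. Its smallest p values belonged to Selp, Gp9 (0.95 ± 0.22) and Vwf (1.57 ± 0.37), genes of platelet adhesion. The list's camera adjusted p was 0.000327, and 0.287 with an estimated correlation. In the HSC-associated list of 24 genes Slamf1 rose and 0 fell, over all genes and adjusted over the list alone; the homeobox gene Hoxb5 had 0.94 ± 0.32. Its camera adjusted p was 0.000414, and 0.504 with an estimated correlation. In the endothelial list of 14 genes 0 passed over all genes and 2 rose adjusted over the list alone, Esam, a junction protein also found on stem cells, at 0.64 ± 0.14 and the transcription factor Sox18 at 1.72 ± 0.48. Camera gave 0.000103, and 0.287 with an estimated correlation. The immediate early list, led by the heat-shock genes Hspa1b and Hspa1a, was placed higher (adjusted p = 4.21e-05; 0.511 with an estimated correlation). The erythroid list was placed lower (0.00014; 0.504), as were the T and NK cell list (0.000327; 0.288) and the monocyte and macrophage list (0.000479; 0.504). In these 4 lists 0 genes passed over all genes or adjusted over the list alone; the smallest p values were those of Slc4a1 and Alas2 (red cell anion exchange and heme synthesis), Gzma and Cd3e (cytotoxic granule and T-cell receptor), and Ccr2 and Ms4a6c (monocyte surface proteins). Smaller adjusted p values than 0.05 were also given to the G2-M (0.022), pyrimidine and 5-FU metabolism (0.0135), glycolysis and hypoxia (0.0156) and histone (0.0486) lists as higher, and to the lymphoid-primed (0.0191), dendritic cell (0.0121) and lineage-gate antigen (0.0253) lists as lower. Their adjusted p with an estimated correlation lay between 0.504 and 0.824. The histone list had a median of 0.07 and a mean of −0.03, so its mean and its test differ in sign.

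After 5-FU, the comparison of mutant with wild type asks whether the substitution alters LSK cells 10 days after the drug. Of the genes tested, 321 passed, 245 higher and 76 lower in the mutant. The share of higher genes (76.3%) was smaller in some alternatives that called more genes: 51.2% in a fit of the 2 groups alone (1064 higher, 1016 lower), 54.9% with the replicate block (836 and 688), 57.4% by limma-voom with sample quality weights (2925 and 2175) and 63.1% by DESeq2 (826 and 482). In others it was not, with 76.7% of 352 genes in a fit that is not robust and 79.2% of 327 with the length trend removed. Some genes of lymphoid-primed progenitors stood among the lower ones, though their list had 4 genes higher and 4 lower and was not called. Flt3, a cytokine receptor of multipotent and lymphoid-primed progenitors, was lower by −2.56 ± 0.29 (adjusted p = 0.00107), with 123 CPM in wild type and 20.9 CPM in the mutant (n = 3 each; chromosome 5, 147330741 to 147400489). Dntt, the enzyme that adds nucleotides where antigen-receptor genes are joined, was lower by −3.48 ± 0.57 (adjusted p = 0.00815), with 79.3 against 7.09 CPM (chromosome 19, 41029275 to 41059525). Dock9, an activator of the GTPase Cdc42, was lower by −1.93 ± 0.28 (adjusted p = 0.00414), with 30.3 against 7.92 CPM. Further named falls were S1pr3 (−3.54), Pdgfrb (−2.96), Atp8b4 (−2.52), Gria3 (−2.14), Nlrc3 (−1.97), Sstr2 (−1.91) and Myh9 (−1.85).

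Of the 12 largest rises in the mutant after 5-FU, most were of genes read at or near 0 in wild type. Fcmr, the Fc receptor for IgM on B cells, had 0 counts in the wild-type 5-FU libraries and 6.46 CPM in the mutant, at least 68.0-fold higher (adjusted p = 0.00815). Rgs4 was at least 97.4-fold, Ccdc184 at least 56.5-fold and Sirpb1a at least 113-fold higher, with floors of 3 counts per library. The V gene Igkv12-89 and the monocyte receptors Cd300e and Sirpb1c had 1 to 3 counts in wild type, and the counting intervals of their folds ran from 5170 to 73300, from 293 to 64500 and from 274 to 60500. Igkv1-117 (0.0595 against 902 CPM), Iglc1 (0.592 against 1420), Iglv1 (2.78 against 1470), the eosinophil ribonuclease Ear2 (0.0405 against 23.9) and the alpha-globin gene Hba-a1 (0.0684 against 20.1) completed the 12. Floors and intervals cover counting error only. After 5-FU no wild-type sample shares its code writing with a mutant sample, so code writing and genotype cannot be separated there by comparing samples. With the writing as a covariate estimated from the PBS groups, 42 genes passed, and 5 of the 24 named genes did, including Fcmr, Dntt, Flt3 and Dock9. With the immunoglobulin share as a covariate, an alternative chosen after the data were seen, edgeR called 0 genes (1591 had an unadjusted p under 0.05). Flt3 (−2.44 ± 0.55), Dntt (−4.60 ± 0.99) and Dock9 (−1.97 ± 0.56) kept about their folds or larger ones there, with wider SE. Of the 24 named genes 3 turned in direction. Leaving out 1 library gave 17 genes (without wild-type replicate 1), 18 (replicate 2), 178 (replicate 3), 145 (without mutant replicate 1), 159 (replicate 2) and 206 (replicate 3); Dntt, Flt3, Gria3 and Dock9 were among those that passed in every such fit.

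**Figure D3:**
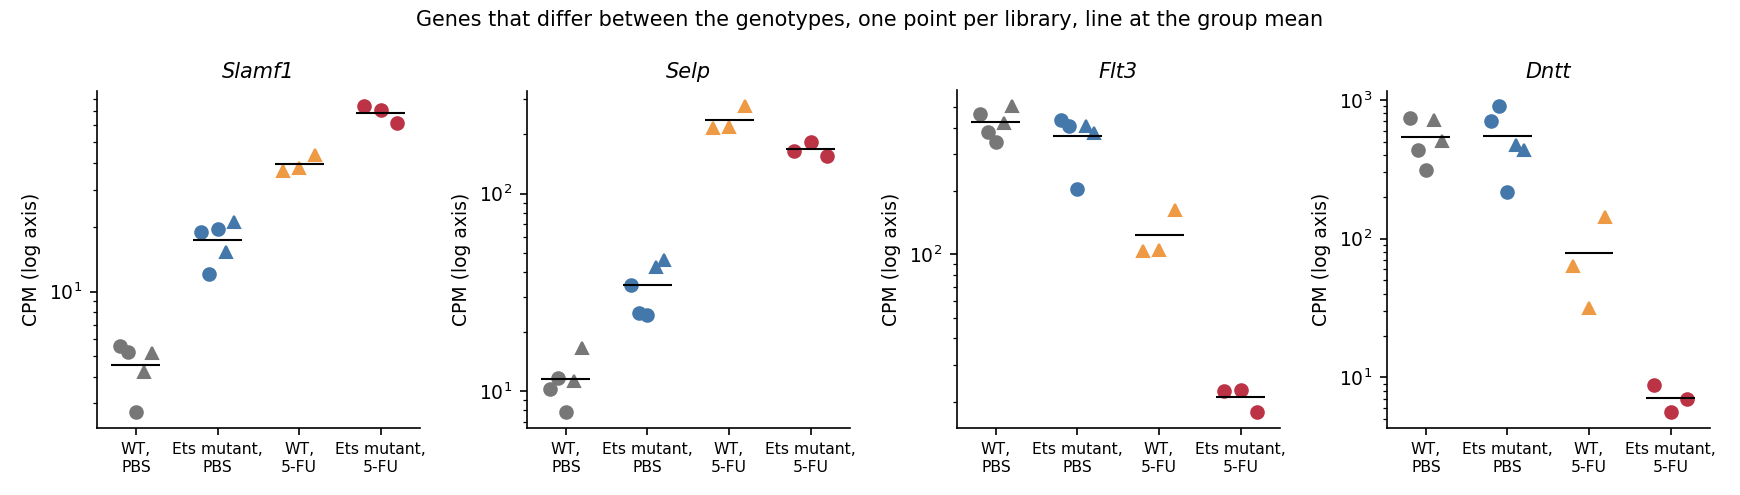
Slamf1, Selp, Flt3 and Dntt in CPM on log axes, a point per library and a line at each group mean; circles carry sample codes with a leading zero and triangles codes without. Slamf1 averages 4.56 CPM in wild-type PBS and 17.5 in mutant PBS libraries, and Flt3 averages 123 CPM in wild-type and 20.9 in mutant 5-FU libraries.

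Camera placed 9 lists higher and 3 lower in the mutant after 5-FU; with an estimated correlation 0 were called. Immune lists stood higher beside the immunoglobulin share of 16.4% against 0.194%. In the B cell list of 13 genes 4 rose, 0 fell and 9 were not past the threshold (7 rose adjusted over the list alone). They included Ms4a1 (0.0304 against 6.30 CPM, counting interval of the fold 64.5 to 922; the CD20 antigen), Pou2af1 (1.36 against 130; a B-cell coactivator) and Cd79a (0.65 against 63.3; a B-cell receptor chain). The list's mean log2 CPM was −1.86 in wild type and 0.95 in the mutant, with a camera adjusted p of 0.00593, and 0.697 with an estimated correlation. In the T and NK cell list of 15 genes 4 rose and 0 fell (6 rose adjusted over the list alone), led by Trbc2 (0.0582 against 3.51 CPM; a T-cell receptor constant region), Il2rb (0.0228 against 6.22, interval 83.6 to 2510; a cytokine receptor chain), Cd2 and Ncr1. Its camera adjusted p was 0.0026, and 0.387 with an estimated correlation; fry, which asks whether the genes of a list move on balance in one direction, gave an adjusted p of 0.01. The monocyte and macrophage list of 16 genes had 2 rises and 0 falls (10 rises and 1 fall adjusted over the list alone), led by Adgre1 (4.50 ± 0.89; the F4/80 antigen). Its camera adjusted p was 0.000148, and 0.697 with an estimated correlation.

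In the immediate early list of 20 genes Klf4 (3.72 ± 0.69) and Fos (5.72 ± 1.34), both rapidly induced transcription factors, rose and 0 fell, with 13 rises adjusted over the list alone; camera gave 1.68e-05, and 0.697 with an estimated correlation. The lymphoid-primed list went both ways, with 4 of 16 genes higher and 4 lower (5 and 6 adjusted over the list alone): Flt3 fell, while Ccr9 (5.81 ± 0.70) and Il7r (6.00 ± 0.82), receptors of lymphoid precursors, rose. Camera did not call it (adjusted p = 0.266). The other higher genes of this list were Ighm, an immunoglobulin gene, and the adaptor gene Blnk. With the immunoglobulin share as a covariate Ighm had −0.32 and Blnk −0.21, against 6.48 for Ccr9 and 3.87 for Il7r. In the list of stem cell cytokine receptors, 22 genes, 1 rose (Il7r) and 3 fell (Flt3, Il1r1 at −1.63 ± 0.34 and Csf2rb2 at −1.84 ± 0.44), and 4 rose and 8 fell adjusted over the list alone. It was placed lower (0.00466; 0.359 with an estimated correlation), and fry gave 0.00941. The HSC-associated list was not called (adjusted p = 0.122), with 0 genes past the threshold and 5 higher adjusted over the list alone, including Slamf1 (0.80 ± 0.25) and Procr (1.00 ± 0.32), an endothelial protein C receptor that marks stem cells. The oxidative phosphorylation (3.8e-08), cytosolic ribosomal protein (5.76e-08) and histone (1.08e-06) lists stood higher with 0, 0 and 1 gene past the threshold, Hist1h2ac at 2.12 ± 0.46, as did the endothelial (0.0135, Stab2 rose) and interferon (0.00466) lists. The G2-M (0.00337, led by Top2a) and ribosome biogenesis and MYC (0.0447, led by Utp20) lists stood lower with 0 genes past the threshold. For these 7 lists the adjusted p with an estimated correlation was 0.697. Members of the oxidative phosphorylation, ribosomal protein and histone lists have short transcripts, and fold changes after 5-FU went with length. Over 16050 genes outside these lists and the immunoglobulin genes, Spearman rho between log2 fold change and effective length was −0.45 after 5-FU, −0.12 under PBS, 0.39 for 5-FU in wild type, 0.14 in the mutant and −0.39 for the interaction. Between genotypes after 5-FU, other genes with lengths in the quartile range of each list had medians of 0.58, 0.63 and 0.59, against 0.71, 0.70 and 1.11 for the lists. With the length trend of each library removed, an alternative chosen after the data were seen, camera gave 0.00817, 0.029 and 0.00378 for the lists, and 0.674, 0.719 and 0.492 with an estimated correlation. A camera test of the edgeR statistics with their trend with length removed did not call them (adjusted p = 0.63, 0.915 and 0.63). Without the length trend of each library 5 further lists were called, the HSC-associated (0.00378), dendritic cell (0.0211) and quiescence (0.0263) lists as higher and the S phase (0.019) and glycolysis and hypoxia (0.04) lists as lower; with an estimated correlation their adjusted p lay between 0.492 and 0.681. The same alternative called 327 genes, with 252 of the 321 among them.

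In wild-type mice, the comparison of 5-FU with PBS asks how LSK cells differ 10 days after the drug. Of the genes tested, 2450 passed, 915 higher and 1535 lower after 5-FU, and 54 of them were immunoglobulin genes. The balance turned by limma-trend on TPM (7179 higher, 510 lower) and was closer to even by limma-voom with sample quality weights (3260 and 3750) and with the replicate block (3489 and 3829). Col18a1, a basement membrane collagen, rose by 5.73 ± 0.58 (adjusted p = 3.27e-05), from 0.805 to 45.5 CPM. Selp rose by 4.36 ± 0.26 (1.62e-07), from 11.5 to 237 CPM. Tgfbr3, a co-receptor for TGF-beta, rose by 3.55 ± 0.37 (4.72e-05), from 8.69 to 102 CPM, and Emilin2, an extracellular matrix glycoprotein, by 3.73 ± 0.58 (0.00102), from 12.9 to 172 CPM. The other named rises were Pde10a (4.41), C4b (4.36), Tmem215 (4.04), Abca4 (3.93), Tjp1 (3.92), Muc1 (3.74), Clca3a1 (3.67) and Sema6b (3.49). Of the 12 largest falls 11 were immunoglobulin genes. All 11 lost their call by limma-voom with sample quality weights, and each did in at least 1 fit without a library, while the other 13 named genes kept theirs in these fits. Ighv7-3 had 0 counts after 5-FU and was at least 2710-fold lower, and Igkv3-2 had 1 to 3 counts with a counting interval of 18000 to 3970000 for its fold. The same interval ran from 6790 to 96200 for Igkv12-89, from 5180 to 1140000 for Ighv3-6, from 5150 to 154000 for Ighv4-1 and from 6740 to 201000 for Igkv6-15. Iglv2 (1800 to 0.0519 CPM), Igkv10-96 (1650 to 0.0494), Igkv17-121 (1450 to 0.0545), Ighg2c (1880 to 0.0924) and Igkv5-43 (837 to 0.0418) fell as well. The neutrophil antimicrobial peptide gene Camp fell from 1180 to 0.0418 CPM (adjusted p = 0.00469). Within libraries that share the code writing 1572 genes passed, within 1 code prefix 189 (with a single wild-type 5-FU library, assumed to vary like the other groups), and with writing as a covariate 1012. The immunoglobulin share as a covariate left 22 genes, and leaving out 1 library gave 1523 (without wild-type PBS replicate 2), 714 (without 5-FU replicate 1), 526 (replicate 2) and 1370 (replicate 3).

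Camera placed 8 lists higher and 15 lower after 5-FU in wild type; with an estimated correlation 0 were called, and fry called 21. In the mature neutrophil list of 15 genes 0 rose and 13 fell (14 adjusted over the list alone). Retnlg, a neutrophil-secreted protein, went from 170 to 0.00887 CPM (1 count, counting interval of the fold 2580 to 568000), Cd177 from 96.0 to 0.136 and the gelatinase gene Mmp9 from 88.7 to 0.457, and the list's mean log2 CPM went from 7.53 to −1.12. Camera gave 4.92e-11, and 0.0914 with an estimated correlation. In the lymphoid-primed list of 16 genes 1 rose and 12 fell, over all genes and adjusted over the list alone, with Ccr9 from 19.4 to 0.115 CPM, Il7r from 16.5 to 0.224, the adaptor gene Blnk from 60.6 to 1.94 and Lsp1 at −1.35 ± 0.17. Camera gave 1.04e-09, and 0.0675 with an estimated correlation. Beside the fall in immunoglobulin share, 12 of 13 genes of the B cell list fell (13 adjusted over the list alone), including Ms4a1 (24.2 to 0.0304 CPM, counting interval of the fold 242 to 3430); camera gave 3.02e-06, and 0.331 with an estimated correlation. In the T and NK cell list 11 of 15 fell (12 adjusted over the list alone), Trbc2 and Lck (−1.97 ± 0.31; a T-cell kinase) among them, with 6.73e-06, and 0.0914 with an estimated correlation. The dendritic cell list had 13 of 15 lower (15 adjusted over the list alone), including Flt3 (−1.78 ± 0.26) and the antigen-presentation genes H2-Aa (−4.44 ± 0.72) and Cd74 (−6.15 ± 1.00). Camera gave 1.3e-08, and 0.0914 with an estimated correlation. The immediate early list had 1 rise and 15 falls of 20 (1 and 19 adjusted over the list alone), led by Klf4, Btg2 and Zfp36, and the monocyte and macrophage list 10 falls of 16 (12 adjusted over the list alone), led by the lysozyme gene Lyz2 (−3.04 ± 0.46). Camera gave 5.07e-08 and 6.13e-06, and 0.336 for both with an estimated correlation.

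Cell-cycle and stem-cell lists stood higher after 5-FU in wild type. The immunoglobulin share and the neutrophil, B cell and T and NK cell lists were lower in the same libraries. A change in the mix of cells was not set apart from a change within cells. In the G2-M list of 26 genes 13 rose and 0 fell (20 rose adjusted over the list alone), led by the mitotic cyclin Ccnb2 (1.02 ± 0.20), Hmmr (1.25 ± 0.28) and the kinesin Kif11 (1.38 ± 0.33); camera gave 3.47e-08, and 0.336 with an estimated correlation. In the S phase list 5 of 25 rose (10 adjusted over the list alone), including the DNA polymerase gene Pola1 (1.22 ± 0.31), with 6.41e-05, and 0.352 with an estimated correlation. In the HSC-associated list 6 of 24 rose and 0 fell (6 and 1 adjusted over the list alone): Slamf1 by 3.11 ± 0.23, the angiopoietin receptor Tek by 2.35 ± 0.34 and Ctnnal1 by 1.88 ± 0.45 were among them. Camera gave 0.00237, and 0.352 with an estimated correlation. In the megakaryocyte and platelet list 5 of 16 rose, over all genes and adjusted over the list alone, led by Selp, Vwf (2.76 ± 0.42), Itga2b (2.56 ± 0.43) and Gp1ba (2.38 ± 0.44), with 0.000772, and 0.176 with an estimated correlation. In the GATA factor and heptad list Zfpm1 (1.63 ± 0.33), Gata1 (1.66 ± 0.37), Gata2 and Fli1 (0.56 ± 0.16), transcriptional regulators of blood cells, rose and 0 of 17 fell (6 rose adjusted over the list alone; 0.0147, and 0.336 with an estimated correlation). The ribosome biogenesis and MYC (4.6e-05), pyrimidine and 5-FU metabolism (0.00391) and glycolysis and hypoxia (0.00483) lists stood higher, with Ddx21, Uck2 and Ldha among the rises. The cytosolic ribosomal protein (3.75e-10), oxidative phosphorylation (2.98e-05), granulocyte-monocyte progenitor (0.00174), erythroid (0.00216), histone (0.00401), lineage-gate antigen (0.02), eosinophil (0.0218) and quiescence (0.0218) lists stood lower, with Rps27, Ndufa4, Cebpe, Rhd, Hist1h1c, Cd3g, Il5ra and Btg2 among the falls. For these 11 lists the adjusted p with an estimated correlation lay between 0.336 and 0.548. With the length trend removed the ribosomal protein (0.137), oxidative phosphorylation (0.134) and histone (0.748) lists were no longer called, and other genes of their lengths had medians of −1.01, −0.83 and −0.87 against −1.13, −0.97 and −1.25. Scaling to the upper quartile moved the median of all genes by −0.13 on the log2 scale, and TPM moved it from −0.11 to 1.19 in this comparison, by −0.79 between genotypes after 5-FU, by 0.42 in the mutant and by −0.89 for the interaction.

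In the mutant, the same question was asked of 5-FU against PBS. Of the genes tested, 362 passed, 138 higher and 224 lower. Col18a1 rose by 4.18 ± 0.54 (adjusted p = 0.000607), from 1.72 to 32.3 CPM, and Rnf128, a ubiquitin ligase, by 4.16 ± 0.47 (0.000176), from 2.31 to 41.3 CPM. Pde10a, a cyclic nucleotide phosphodiesterase, rose by 4.05 ± 0.60 (0.00191), and Ripor3 by 5.16 ± 0.86 (0.00383). The killer-cell receptor Klrg1 (0.0566 to 5.84 CPM), S1pr5 (0.119 to 8.77), Cd300e (0.272 to 15.7), Ace (0.179 to 8.75), Treml4 (0.658 to 22.4), Bcl2a1a (0.303 to 5.73), Nmur1 (0.446 to 8.13) and Igkv4-69 (0.135 to 1150) completed the 12. The 12 largest falls were led by genes of granulocytes. Prss34, a basophil protease, went from 42.6 CPM to 0 counts, at least 420-fold lower (adjusted p = 0.00665), and Retnlg from 115 to 0.115 CPM (8.66e-05). Ly6g, the neutrophil surface marker, and Orm1 had 1 to 3 counts after 5-FU, with counting intervals of 230 to 6870 and 43.9 to 627 for their folds. Ngp (2030 to 4.47 CPM), Cd177 (71.3 to 0.148), Mmp8 (59.5 to 0.152), Fcnb (73.9 to 0.222), Chil3 (447 to 1.41), Ltf (562 to 2.04), Wfdc21 (86.3 to 0.38) and Itgb2l (17.9 to 0.0846) fell as well. Within libraries that share the code writing 178 genes passed, within 1 code prefix 294, and with writing as a covariate 887. Leaving out mutant 5-FU replicate 2 or 3 left 179 and 156 genes, and 10 of the 24 named genes lost their call in at least 1 fit without a library: Igkv4-69, Klrg1, S1pr5, Cd300e, Ace, Treml4, Bcl2a1a, Nmur1, Mmp8 and Wfdc21.

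Camera placed 7 lists higher and 11 lower after 5-FU in the mutant, and 3 of these calls held with an estimated correlation. In the lymphoid-primed list 0 of 16 genes rose and 8 fell (11 adjusted over the list alone): Flt3 by −4.13 ± 0.30 (366 to 20.9 CPM), Dntt by −6.27 ± 0.63 (548 to 7.09 CPM), the chromatin organizer Satb1 by −3.19 ± 0.35 and the recombinase gene Rag2 by −5.25 ± 0.84. Camera gave 3.83e-17, and 0.00345 with an estimated correlation. In the mature neutrophil list 9 of 15 fell and 0 rose (14 fell adjusted over the list alone), Mmp9 by −6.13 ± 0.94 among them, with 5.74e-23, and 0.00345 with an estimated correlation. In the megakaryocyte and platelet list Selp (2.28 ± 0.24) and Vwf (1.71 ± 0.41) rose and 0 of 16 fell (5 rose adjusted over the list alone), with 4.4e-06, and 0.0385 with an estimated correlation (0.0806 with the length trend removed as well). The HSC-associated list had 4 rises of 24 and 0 falls (8 and 2 adjusted over the list alone): Slamf1 by 1.98 ± 0.22, Clca3a1 by 2.87 ± 0.61, Ctnnal1 by 2.09 ± 0.45 and Tek by 1.52 ± 0.34. Camera gave 4.86e-06, and 0.262 with an estimated correlation. The endothelial list stood higher with Esam (1.47 ± 0.16) and Tek past the threshold (2.63e-05, and 0.151 with an estimated correlation). The granulocyte-monocyte progenitor list stood lower with Cebpe past it (−4.91 ± 0.96; 1.44e-07, and 0.223 with an estimated correlation). The immediate early (1.25e-08, Btg2 fell), dendritic cell (1.74e-06, Flt3 and Siglech fell) and B cell (8.99e-05, Rag1 and Ighd fell) lists stood lower; with an estimated correlation their adjusted p values were 0.313, 0.166 and 0.313. The immunoglobulin share averaged 25.9% before and 16.4% after 5-FU. The G2-M (0.00432), ribosome biogenesis and MYC (0.0309), S phase (0.0358) and pyrimidine and 5-FU metabolism (0.0478) lists stood higher with 0 genes past the threshold, and the lineage-gate antigen (0.00822), cytosolic ribosomal protein (0.0175), eosinophil (0.0225), quiescence (0.0306) and erythroid (0.0317) lists lower. Their adjusted p with an estimated correlation lay between 0.262 and 0.913. With the length trend removed the ribosomal protein list had an adjusted p of 0.748, and the ribosome biogenesis, S phase, pyrimidine, quiescence and erythroid lists each had 0.052; the oxidative phosphorylation list was then called as higher (3.53e-05, and 0.536 with an estimated correlation), but not by the test of the edgeR statistics (adjusted p = 0.63).

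The 5-FU effects in the 2 genotypes share no libraries and could be compared. Of 16482 genes, 81 rose in both where 7.7 would by independence, among them Selp, Slamf1, Vwf, Gata1, Tek, Esam, Hoxb2, Col18a1 and Pde10a. In both, 165 fell against 20.9 by independence. Only 1 gene rose in wild type and fell in the mutant, and 9 fell in wild type and rose in the mutant, against 12.4 and 12.9. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.43.

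The interaction asks whether the response to 5-FU differs between the genotypes. It passed the threshold for 97 genes; 92 had a more positive and 5 a more negative response in the mutant. The 5 included Flt3 (−2.35 ± 0.35, adjusted p = 0.00798), Dock9 (−2.04 ± 0.34, 0.0135), Selp (−2.09 ± 0.35, 0.0141) and Dntt (−3.50 ± 0.67, 0.0266). Flt3 and Dntt fell in both genotypes and fell further in the mutant, and Selp rose in both and rose less in the mutant, from 34.4 to 167 CPM against 11.5 to 237 CPM in wild type. The 12 named genes among the 92 averaged at most 0.187 CPM in the wild-type 5-FU libraries and at least 0.303 CPM in each other group. Il2rb averaged 3.76, 0.929, 0.0228 and 6.22 CPM in wild-type PBS, mutant PBS, wild-type 5-FU and mutant 5-FU (adjusted p = 0.00798), and the B-cell gene Ms4a1 24.2, 16.7, 0.0304 and 6.30 CPM (0.0117). Ikzf3, a lymphocyte transcription factor, averaged 33.4, 31.9, 0.0735 and 21.4 CPM (0.0266), and Rasgrp1, an activator of Ras in lymphocytes, 2.13, 0.869, 0.0266 and 8.72 CPM (0.00798). The other named genes of the 92 were Trbc1, Fcmr, Tcrg-C4, Blk, Treml4, Bcl2a1a, Bcl2a1d and Igkv1-117. With code writing as a covariate 27 genes passed and 8 of the 17 named genes, and with the immunoglobulin share as a covariate edgeR called 0 (1474 with an unadjusted p under 0.05). With that share as a covariate Flt3 (−2.22), Dock9 (−2.07), Dntt (−4.67), Il2rb (10.18) and Rasgrp1 (9.04) kept folds about as large or larger. Those of Selp (−1.06), Ms4a1 (3.04) and Ikzf3 (1.58) shrank. Leaving out 1 library gave 11 to 309 genes, with 51, 62, 309 and 59 without mutant PBS replicates 1, 2, 3 and 4 and 11, 15 and 41 without wild-type 5-FU replicates 1, 2 and 3; of the 17 named genes, Flt3 and Trbc1 passed in every such fit.

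**Figure D4:**
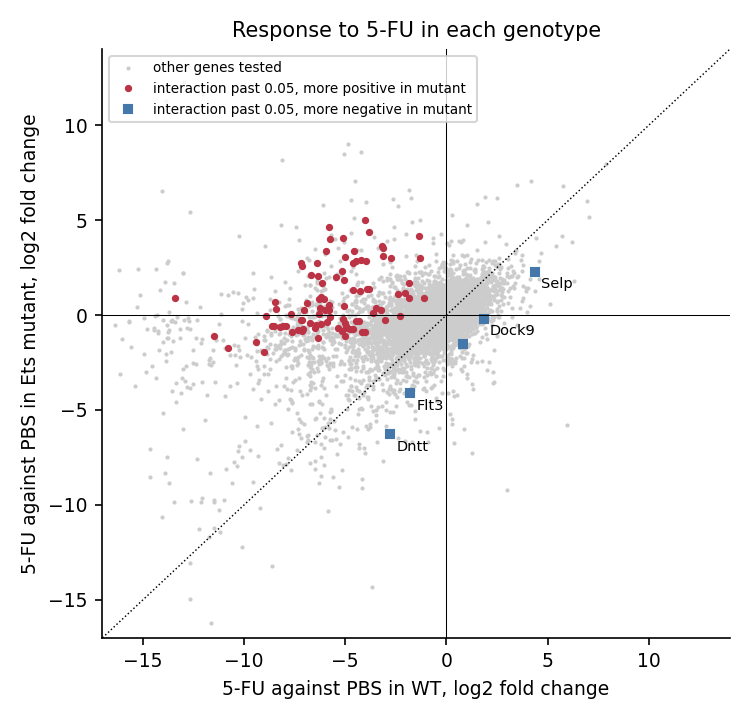
Log2 fold change after 5-FU in wild type (horizontal axis) and in the mutant (vertical axis), a point per gene tested; red points and blue squares mark genes past the interaction threshold with a more positive or more negative response in the mutant, and the dotted line marks equal responses. Of the 97 marked genes 92 are red, and the 5 blue squares include Flt3, Dntt, Selp and Dock9.

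Camera placed 10 lists more positive and 7 more negative for the interaction; with an estimated correlation 0 were called. In the T and NK cell list 4 of 15 genes were more positive and 0 more negative (8 adjusted over the list alone), Trbc2, Il2rb, Cd2 and Ncr1. Camera gave 2.11e-05, and 0.404 with an estimated correlation, while fry gave 0.0292. In the B cell list 3 of 13 were more positive (7 adjusted over the list alone), Ms4a1 and Pou2af1 among them, with 0.000558, and 0.628 with an estimated correlation. In the monocyte and macrophage list Adgre1 (5.29 ± 1.05) was more positive (8 of 16 adjusted over the list alone), with 4.58e-07, and 0.442 with an estimated correlation. The lymphoid-primed list again went both ways, with 4 of 16 more positive and 3 more negative (4 and 4 adjusted over the list alone), and was not called (adjusted p = 0.598). Its more positive genes were Ccr9, Il7r, Ighm and Blnk. With the immunoglobulin share as a covariate they had 7.28, 4.43, −0.37 and −0.04 in that order. The HSC-associated list was not called either (0.652); Slamf1, at −1.13 ± 0.32, had an adjusted p of 0.138. The cytosolic ribosomal protein (1.55e-06), oxidative phosphorylation (1.55e-06), histone (0.000183), interferon (0.000846), immediate early (0.00325, with Klf4 past the threshold), dendritic cell (0.00779) and erythroid (0.0247) lists were more positive. The G2-M (8.3e-05), S phase (0.00779), ribosome biogenesis and MYC (0.00779), glycolysis and hypoxia (0.00783), GATA factor and heptad (0.0124), stem cell cytokine receptor (0.0247, with Il7r past the threshold as more positive and Flt3 as more negative) and GATA2-linked (0.0279) lists were more negative. For these 14 lists the adjusted p with an estimated correlation lay between 0.442 and 0.628. With the length trend removed the ribosomal protein (0.233), oxidative phosphorylation (0.0766), histone (0.101) and stem cell cytokine receptor (0.152) lists were no longer called. Without mutant 5-FU replicate 1, 9 lists passed.

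**Figure D5:**
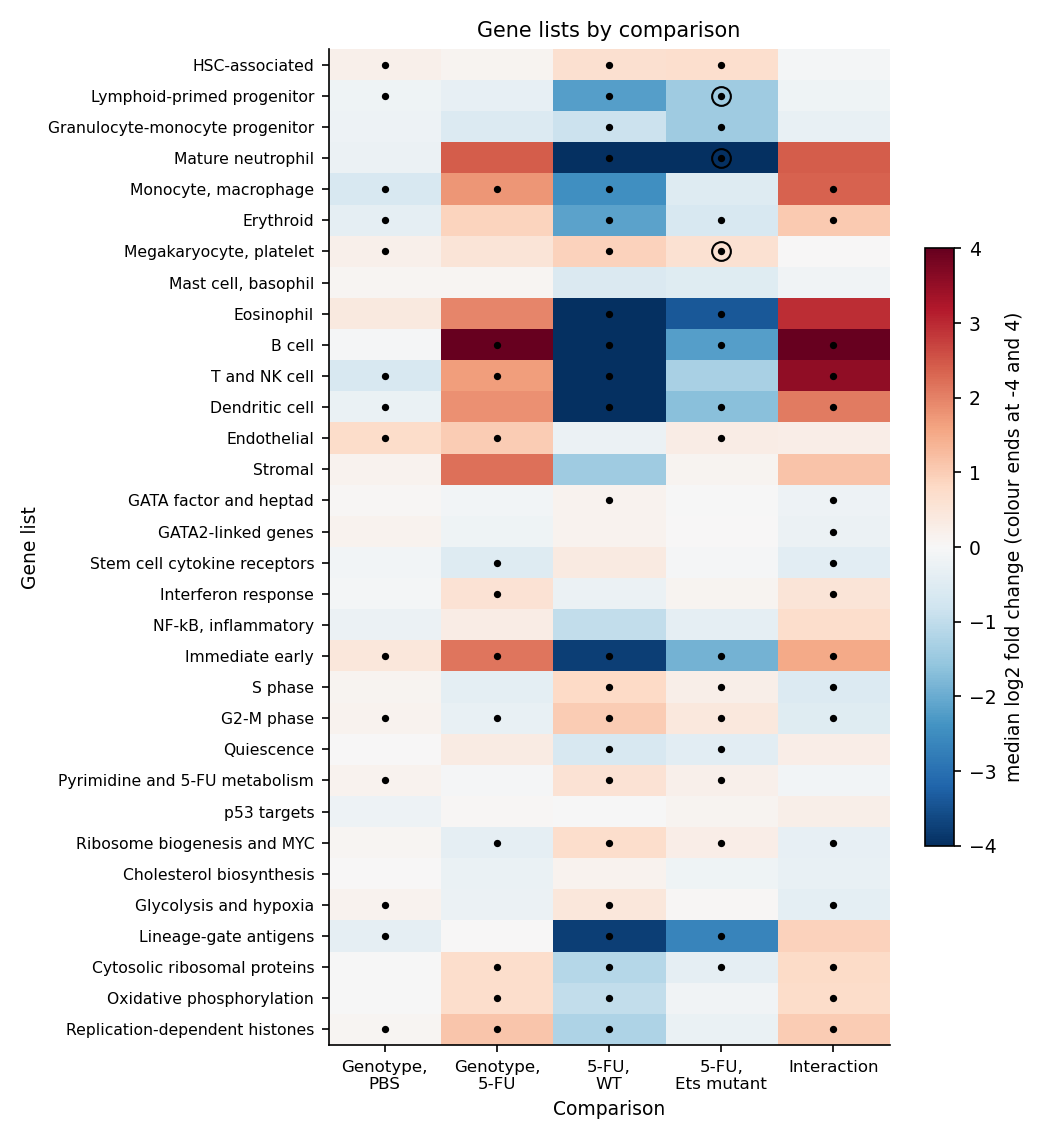
Median log2 fold change of each gene list (vertical axis) in the 5 comparisons (horizontal axis), with colours ending at −4 and 4; a dot marks a camera adjusted p under 0.05 and a ring a call that also held with an estimated correlation. The 3 rings are the lymphoid-primed, mature neutrophil and megakaryocyte lists after 5-FU in the mutant.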

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

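For 2 of the 3 patterns weighed here (the immunoglobulin transcripts and the 3 genes higher under PBS), and for the dilution, length and code-writing tests of the remaining pattern (the 321 genes), the tests were chosen after the result was seen; the test for genes of other cell types was set before its result was seen.

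Immunoglobulin genes held 3.67 to 50.2% of counts in the PBS libraries and 0.04 to 0.33% in the wild-type 5-FU libraries, although the sort removes B220-positive cells. Antibody-secreting cells among the sorted cells are a candidate source: over the 10 PBS libraries the log2 share rose with the mean log2 CPM of 25 plasma cell genes that are not immunoglobulin genes, with Spearman rho 0.96 (permutation p = 8e-05; Pearson r 0.97, permutation p = 1e-05, the smallest the draws can give; 8e-05 and 2e-05 after adjustment over the family of 2), r 0.95 without the 2 farthest libraries, and 0.98 in each group of code writing (6 and 4 libraries). Of these genes Sdc1 averaged 240 CPM in wild-type PBS and 14.5 in wild-type 5-FU libraries, Slamf7 144 and 0.618, and Irf4 64.3 and 0.458. A batch marked by the writing of the sample codes is argued against for the drop after 5-FU in wild type, since among libraries with the same writing the share was 81.6-fold lower after 5-FU (15.8%, n = 2, against 0.194%, n = 3). For the spread among PBS libraries such a batch stays open: every library with a leading zero (lowest 28.94%) lay above every library without (highest 25.24%), with an exact two-sided permutation p of 0.01 over 100 assignments within genotype, and biological differences between the mice were not tested.

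After 5-FU 321 genes differed between the genotypes. Fewer LSK cells in the mutant sort would lower all genes of LSK cells by about as much. The 24 HSC-associated genes had a median log2 fold change of 0.10 (quartiles −0.25 and 1.02), so they did not fall as a set. This was 1.55 above the −1.45 of the 76 lower genes and beyond the quartile range of 1.27 (1.45 and 0.88 with the length trend removed). The 76 genes were picked for their fall in this comparison, so their median lies low by choice. The gate genes went both ways, with Kit at −1.47 and Ly6a at 1.7 in mean log2 CPM (exact two-sided permutation p = 0.1 each). Dilution is therefore not decided as a cause of the 76 lower genes. A bias with transcript length is argued against as the whole cause, since 252 genes stayed past the threshold in the same direction without the length trend, 45 of them among the 76 lower genes. A batch cannot be told apart from genotype here, since code writing and genotype coincide after 5-FU: with writing as a covariate estimated from PBS libraries the median of the 76 genes was −1.05, all 76 stayed lower, and 7 stayed past the threshold as the median SE went from 0.30 to 0.34 and the fold shrank, while with the immunoglobulin share as a covariate the median was −0.49, 66 stayed lower, 0 passed (edgeR), and the median SE was 0.54. Genes of other cell types may account for part of the 245 higher genes, of which 240 are not immunoglobulin genes. Of these 240, 51.2% had rho above 0.5 with the immunoglobulin share over the PBS libraries, against 27.8% of 16285 genes and 2.63% of the lower genes. The share fell short of the multiple of that of all genes set beforehand, so the test does not decide. Wild-type and mutant PBS replicates 3, highest in immunoglobulin share (44.24 and 50.17%), also had the lowest mean effective length of other genes (942 and 958). Length was not set apart in this test, and a change within LSK cells stays open too.

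Under PBS Slamf1, Hoxb2 and Selp were higher in the mutant. That the 3 genes lie within DNA carried along with the edited allele is argued against, because 0 of the 3 genes lie on the chromosome of Gata2. An effect of such DNA on genes of other chromosomes was not tested. Slamf1 and Selp share a chromosome. For a larger share of stem-like cells in the mutant sort, the other 23 HSC-associated genes had a median of 0.21 (quartiles −0.05 and 0.46, 16 positive), against 1.92 for the 3 genes. The 3 genes were picked as those past the threshold, so their median is high by choice. Camera placed the HSC-associated list higher (adjusted p = 0.000414), but not with an estimated correlation. These values therefore do not decide whether such cells account for the 3 genes. A biological effect of the substitution on these genes and a difference between litters or days, which the labels do not record, stay open.

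The number of genes called was also counted for other splits of the samples. These counts and the rule for reading them were set after the data were seen. Under PBS the replicate numbers were taken to pair the samples, from correlations in these same data. Of the 16 splits that part all 5 pairs, 1 gave as many genes, the real one. The 16 splits are too few for a share under 0.05 (real 3, highest other 0). Of 100 splits drawn without regard to the pairs 3 gave as many genes, and the 2 others parted only 1 pair. The highest of these called 5207, several times the real count, which points to a structure of the samples, as it set 5 libraries whose codes have a leading zero (wild-type PBS replicates 2 and 3, mutant PBS replicates 1 to 3) against the rest. With writing as a covariate the real comparison under PBS called 4 genes. The splits themselves were fitted without this covariate. After 5-FU 1 of 10 splits did, the real one; 10 splits are too few for a share under 0.05 (real 321, highest other 4). For 5-FU in wild type 1 of 56 splits gave as many genes, the real one (real 2450, highest other 1558). The highest other set wild-type PBS replicates 1 to 3 against the rest, which is the code writing, and 1572 genes passed within 1 writing. For 5-FU in the mutant it was also 1 of 56, the real one (real 362, highest other 8). A share of 0.0179 is the smallest that 56 splits can give, so it speaks against chance without excluding it. For the interaction 2 of 84 regroupings drawn that keep the PBS pairs gave as many genes (real 97, highest other 153), a share of 0.0238 that does not exclude chance either. The count went with the parting of the 5-FU libraries, though, for which 10 splits are too few: the 9 other regroupings that part them by genotype called 33 to 153 genes, and the 74 that do not called at most 3. Of 100 regroupings drawn without regard to the pairs 4 gave as many genes, and the highest other called 1578, again many times the real count, which points to a structure of the samples.

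Other results stood out by rule. Of 234 groups of values 17 had a library far from the others, where chance gives about 1 in 20 groups, or 11.7; 6 of the 17 were in mutant PBS replicate 3 and 3 in wild-type PBS replicate 3. In mutant PBS replicate 3 these were S1pr3 (1.41 CPM), Flt3 (204 CPM), Sstr2 (9.86 CPM), Wfdc21 (294 CPM) and the mean log2 CPM of the mature neutrophil (8.31) and S phase (5.53) lists. In wild-type PBS replicate 3 they were S1pr3 (1.27 CPM), Prss34 (73.9 CPM) and the granulocyte-monocyte progenitor list (7.79). Wild-type PBS replicate 5 had Igkv10-96 at 0.184, Igkv4-69 at 55.4 and Ikzf3 at 6.83 CPM, and mutant PBS replicate 5 had Igkv1-117 at 0.597, Ighv7-3 at 0.0373 and Ighg2c at 0.597 CPM. Tgfbr3 in mutant PBS replicate 2 (7.23 CPM) and the NF-kB list in wild-type PBS replicate 2 (2.94) completed them.

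The response to 5-FU differed between the genotypes, by the interaction test, for 97 genes and, by camera with the preset correlation, for 17 lists; an estimated correlation left 0 of these lists and fry called 1. The interaction log2 fold changes of named genes included 14.30 for Igkv1-117, 10.36 for Fcmr, 9.89 for Il2rb, 9.77 for Tcrg-C4, 9.30 for Rasgrp1, 9.07 for Blk, 9.04 for Treml4, 8.74 for Trbc1, 8.17 for Bcl2a1a, 8.06 for Bcl2a1d, 8.04 for Ikzf3 and 7.99 for Ms4a1, and −3.50 for Dntt, −2.35 for Flt3, −2.09 for Selp and −2.04 for Dock9. The positive ones rest on wild-type 5-FU libraries at or near 0 counts, so their sizes are not bounds. Since code writing coincides with genotype after 5-FU, these values do not set a differing response apart from a batch. A difference in the mix of cells was not set apart either.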

How the results depend on the processing

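The immunoglobulin share as a covariate, immunoglobulin genes left out, the joint omission of wild-type PBS replicate 3 and mutant PBS replicate 3, the replicate block in the PBS groups alone and the length trend removed were tests chosen after the data were seen; the other alternatives were set beforehand. Counts of genes below are in the order genotype under PBS, genotype after 5-FU, 5-FU in wild type, 5-FU in the mutant and interaction, against 3, 321, 2450, 362 and 97, and the cause of a change was not tested unless stated. RLE and upper-quartile scaling, no filter, a filter of 1 CPM, a fit that is not robust, the 2-fold minimum, sex-linked genes left out and immunoglobulin genes left out kept every count within 1.5 times.

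DESeq2 called 26, 1308, 4597, 887 and 581 genes, and limma-voom with sample quality weights 9, 5100, 7010, 1556 and 723. Limma-trend on TPM called 0 (119 with an unadjusted p under 0.05), 107, 7689, 116 and 52; its calls in wild type were 93.4% higher against 37.3% in the edgeR test, with the median of all genes at 1.19 against −0.11, and in the mutant 61.2% against 38.1%. A filter of 5 CPM, which tests fewer genes, gave 197 after 5-FU and 60 for the interaction. Only the 2 groups compared, a fit with fewer samples, gave 0 under PBS by edgeR (318 with an unadjusted p under 0.05), 2080 between genotypes after 5-FU and 210 in the mutant. With code writing as a covariate 42, 1012, 887 and 27 genes passed for the last 4 comparisons. Within a single code prefix 189 passed in wild type, and within a single code writing 1572 in wild type and 178 in the mutant. With the immunoglobulin share as a covariate 0 genes passed after 5-FU (1591 with an unadjusted p under 0.05), 22 in wild type and 0 for the interaction (1474). After 5-FU and for the interaction Flt3 (−2.44 and −2.22), Dntt (−4.60 and −4.67) and Dock9 (−1.97 and −2.07) kept about their folds or larger ones. The named genes that turned in direction are given below. Without wild-type PBS replicate 3 and mutant PBS replicate 3 the counts were 1077 after 5-FU, 683 in the mutant and 255 for the interaction, and those of the other comparisons stayed within 1.5 times.

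Removing the length trend gave 609 genes in the mutant and kept the other counts within 1.5 times; of the lists called it kept 14 of 14, 12 of 12, 20 of 23, 12 of 18 and 13 of 17, and added 1, 5, 3, 1 and 0. With an estimated correlation it left 0, 0, 0, 2 and 0 lists. Gata2 between genotypes after 5-FU turned to 0.01.

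A replicate block gave 3 genes under PBS, where the numbers were taken to pair the samples, and 1 in the PBS groups alone, a fit with fewer samples. In the fit of all groups it changed no call of a named gene under PBS, and 15 lists passed against 14. The 5-FU samples share only a number: of the 15 other same-numbered pairs 3 had r over 0.1, and no pair of groups but the PBS groups had r over 0.1 throughout. For the last 4 comparisons the block gave 1524, 7318, 1014 and 383 genes. Of the 10 PBS samples 9 correlated best with their own number, which is a hint from the data and not from the design; over all 20 pairs 8 had r over 0.1, with a range of −0.16 to 0.57 and medians of 0.04 for same-numbered and −0.04 for other pairs.

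Leaving out single libraries gave 1 to 4, 17 to 206, 526 to 3233, 156 to 405 and 11 to 309 genes. The counts that moved over 1.5 times were 1 without wild-type PBS replicate 4 under PBS; 17, 18 and 178 without wild-type and 145, 159 and 206 without mutant 5-FU replicates 1, 2 and 3 after 5-FU; 1523 without PBS replicate 2 and 714, 526 and 1370 without 5-FU replicates 1, 2 and 3 in wild type; 179 and 156 without 5-FU replicates 2 and 3 in the mutant; and, for the interaction, 51, 62, 309 and 59 without mutant PBS replicates 1 to 4 and 11, 15 and 41 without wild-type 5-FU replicates 1 to 3. Each such fit has fewer samples.

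Gata2 turned direction between genotypes after 5-FU with code writing (0.82) and with the immunoglobulin share (1.78) as covariates, in wild type with the immunoglobulin share (−0.59), and for the interaction with both (0.27 and 1.33). It lost its call in wild type within a single code prefix (0.97), a fit with 1 wild-type 5-FU library, and gained one in the mutant with voom quality weights (0.83), the replicate block (1.28) and code writing (1.24). Without single libraries its log2 fold change ran from 0.42 to 0.82, −0.18 to −0.03, 1.39 to 1.69, 0.55 to 0.96 and −0.95 to −0.53; without wild-type 5-FU replicate 2 it was 1.43 in wild type with an adjusted p of 0.0581.

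Of the gene lists, 14, 12, 23, 18 and 17 passed with the preset correlation. An estimated correlation left 0, 0, 0, 3 and 0, and fry 0, 2, 21, 8 and 1. The immunoglobulin share as a covariate left 14 in wild type and code writing 8 for the interaction. Without single libraries the numbers ran from 10 to 20, 9 to 17, 21 to 25, 12 to 18 and 9 to 19, with 9 for the interaction without mutant 5-FU replicate 1.

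Among named genes the log2 fold change of Ly6a under PBS turned to 0.01 with voom quality weights and ran from −1.06 to 0.77 without single libraries, with 0.77 without wild-type replicate 3, 0.13 without mutant replicate 4 and 0.15 without mutant replicate 5. With code writing as a covariate Ly6a turned to −1.07 between genotypes after 5-FU and −0.65 for the interaction, and Kit to 0.23 in the mutant and 0.19 for the interaction; the replicate block gave Kit 0.26 in the mutant. With the immunoglobulin share as a covariate the turned values were, between genotypes after 5-FU, 1.43 for Kit, −4.30 for Ly6a, −0.54 for Iglv1, 0.51 for Nlrc3 and 0.01 for Myh9; in wild type −2.39 for Kit, 4.46 for Ly6a, 6.86 for Igkv10-96 and 1.5 for Igkv6-15; in the mutant 0.19 for Ly6a; and for the interaction 1.98 for Kit and −4.27 for Ly6a. Of the named genes past the threshold, code writing as a covariate kept 3 of 3, 5 of 24, 18 of 24, 24 of 24 and 8 of 17, and 1, 5, 13, 14 and 2 passed whichever single library was left out. Depth limits the genes at or near 0 counts, whose folds have floors of 0.0798 to 0.272 CPM.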

Other observations

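The tests reported in this part were chosen after the data were seen, apart from the fit without sex-linked genes and the gene lists. These were set beforehand, with the exception of the plasma cell list.

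Most immunoglobulin transcripts were of the IgM class, which made up between 62.6 and 98.6% of heavy-chain constant region counts in the 16 libraries. In wild-type PBS replicates 1, 2, 3 and 5 and mutant PBS replicates 1, 2, 3, 4 and 5 the leading kappa V gene was Igkv14-126, with 22.1 to 65.6% of kappa V counts, and in 7 of these libraries the leading heavy V gene was Ighv11-2, a pair known from natural IgM of B-1a cells. In mutant PBS replicate 4 these genes held 65.6 and 57.3%. Wild-type PBS replicate 4 was led by Igkv1-88 (45.7%) and Ighv5-16 (69.9%), and mutant 5-FU replicate 3 by Igkv4-69 (37.3%) and Ighv1-49 (33.7%). After 5-FU the pair also led mutant replicate 1 (43.9 and 43.4%), and Igkv14-126 led mutant replicate 2 (15.9%, beside Ighv5-16 at 14.4%) and wild-type replicate 3 (56.8%, beside Ighv1-64 at 40.6%). Wild-type 5-FU replicates 1 and 2 were led by Igkv12-41 (55.7%) and Igkv15-103 (56.1%), with Ighv1-49 (79.0%) and Ighv7-1 (48.0%). V genes share reads with near copies, so these shares are uncertain.

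The list of 25 plasma cell genes without immunoglobulin genes had 20 falls and 1 rise after 5-FU in wild type (24 and 1 adjusted over the list alone), including Sdc1, the syndecan that marks plasma cells, at −4.05 ± 0.63, and Irf4 (64.3 to 0.458 CPM), a transcription factor they need. Camera gave an adjusted p of 2.58e-10, and 0.344 with an estimated correlation. Between genotypes after 5-FU 8 of its genes were higher in the mutant (19 adjusted over the list alone; camera 6.2e-11, and 0.689 with an estimated correlation), and in the mutant 0 genes passed by edgeR and camera gave 0.511. Under PBS camera gave 0.0194 with 0 genes past the threshold by edgeR, and for the interaction 3.7e-14 with 1 rise, Irf4; with an estimated correlation these were 0.818 and 0.531.

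The p53 target, cholesterol biosynthesis, mast cell and basophil, stromal and NF-kB lists were called in no comparison by camera with the preset correlation in the fit without a block or covariate. The p53 target list had 2 falls of 21 after 5-FU in wild type, Trp53inp1 (−2.17 ± 0.59), an autophagy and cell-death gene, and the kinase gene Plk2 (−4.13 ± 1.28), with a camera adjusted p of 0.797. Trp53inp1 is also in the plasma cell list. The cholesterol biosynthesis list had 0 genes past the threshold in any comparison; its camera adjusted p was 0.588 in wild type and 0.124 in the mutant. In the mast cell and basophil list Hdc, the histamine-forming enzyme, had a log2 fold change of −3.85 ± 0.73 in the mutant and Prss34 fell in both genotypes, with camera adjusted p values of 0.642 in wild type and 0.517 in the mutant. In the stromal list the osteopontin gene Spp1 rose by 1.51 ± 0.45 in wild type (camera 0.847). In the NF-kB list the chemokine genes Ccl3 (−8.16 ± 0.92 in wild type, −6.87 ± 0.87 in the mutant) and Ccl4 fell and Bcl3 and Nfkb1 rose in both genotypes, with camera adjusted p values of 0.0805 and 0.791, and 0.0437 in wild type with the length trend removed. The list of 18 GATA2-linked genes had 4 rises after 5-FU in wild type (camera 0.0996) and 1 rise and 1 fall in the mutant (camera 0.916), and was placed more negative for the interaction (camera 0.0279, and 0.628 with an estimated correlation).

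Y-linked transcripts were read in wild-type PBS replicates 1 and 2, mutant PBS replicates 1 and 2, wild-type 5-FU replicates 1 and 2 and mutant 5-FU replicate 3, and Xist in the other libraries. The labels do not give the sex of the mice. Leaving out the sex-linked genes gave 3, 323, 2454, 363 and 98 genes past the threshold in the 5 comparisons. This does not adjust the other genes for sex, and no fit held sex as a covariate. After 5-FU the sex-linked transcripts were not balanced between the genotypes.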
